A study of Homo sapiens with 4 samples.

How the data were processed

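RNA was extracted with the MagZol reagent, messenger RNA was captured on beads, fragmented and turned into adapter-ligated double-stranded cDNA, per the labels' protocols. One library was sequenced for each of 2 siRNAs in each of 2 cisplatin-resistant lines, 4 libraries in all, 24 h after transfection. The submitters' processing notes name fastp 2.0, HISAT2 2.1.0, StringTie, DESeq2 and edgeR, without saying what each was used for. The genome build and annotation release are not given in the sources used here, nor is whether counting used the strand. Reads of a gene and of an antisense partner may therefore be mixed in these values.

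For each line the authors deposited a table of the genes marked significant, with FPKM per library, a log2 fold change, a p-value, an adjusted p-value, gene coordinates and gene length, per the file headers. A second pair of columns repeats the FPKM values in all 440 and 420 genes. The deposited log2 fold change equals the log2 ratio of FPKM + 0.01 in every gene (largest deviation 5.3e-15). Its smallest absolute value was 1.00 in both tables, and the largest deposited adjusted p was 0.0186 for A2780_DDP and 0.0136 for SKOV-3_DDP. Other genes, KRT14 among them, were not analysed here, and listed means present in the tables as used here. The ratio of raw to adjusted p-values in the authors' deposited table recovers the number of genes they tested, assuming the Benjamini-Hochberg method. It was 13495 for A2780_DDP and 14574 for SKOV-3_DDP, the totals with the most whole ranks in the range scanned. Multiples of these totals would fit as well. With these totals 94.1% and 97.1% of listed genes fall on a whole rank.

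Groups follow the sample titles, which also name the columns of the tables. From the FPKM values, log2((FPKM + 1)/(FPKM + 1)) was computed per gene and line, library titled siKRT14 over library titled siNC, and fold changes are given on that scale, which understates the change of low genes. Genes were counted when the mean FPKM of the 2 libraries was at least 5 and the ratio at least 2-fold. Because the tables hold FPKM of called genes alone, with 1 library per group, no test was run. The planned model over both lines was to be left out for tables of called genes and was not run. The percentiles of gene list medians among random lists and the count-based normalizations were not run because they need the other genes or counts. In place of list medians, listed members of 35 gene lists were counted in each direction. Genes were named by a rule fixed before the data were examined: KRT14 and LRP11, the 10 highest and 10 lowest ratios per line among genes with a symbol and a mean of at least 5 FPKM, up to 10 genes per direction with the largest smaller ratio of both lines, and up to 4 members per list at that mean. List members under that mean are also named where a list had few. Some genes that the rule selects are not reported here.

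Gene IDs were matched to GENCODE 29 (GRCh38). In A2780_DDP 422 of the 440 IDs were found, all overlapping their locus, and 355 had the same start or end. In SKOV-3_DDP these numbers were 408 of 420 and 337. Coordinates are printed as in the tables. A gene was called overlapping when an exon shares at least 1 base with an exon of another gene on the same strand, which held for 28.0% of matched genes in A2780_DDP and 33.3% in SKOV-3_DDP. Loci absent from GENCODE 29 are not seen by this rule, so a gene called free of overlap may still overlap such a locus. Named pseudogenes are genes of that annotation with the symbol followed by P and a number.

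Depth was estimated from the FPKM values: for genes whose FPKM times length in kilobases was under 8, that product was scanned over totals between 15000000 and 45000000 fragments for the one that gives whole fragments (within 0.03) most often. The best totals made 31.4%, 30.4%, 24.0% and 26.6% of 204, 207, 200 and 177 genes whole, where the average total gives 6.00%. The next best totals made 20.6%, 18.4%, 15.5% and 19.8% whole. They lay at 1.50 times the best total in both A2780_DDP libraries, next to it (0.999 times) in SKOV-3_DDP-siKRT14 and at 0.500 times in SKOV-3_DDP-siNC, and multiples of the best totals can fit as well. As most genes did not come out whole, no counts were derived for a test. On simulated values with 20% or 33% of genes made whole, 5 of 5 known depths were found for each library, and with 0% made whole the best totals reached at most 14.9% in A2780_DDP and 14.4% in SKOV-3_DDP. The number of tests was found in 1 of 1 simulation for each line. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were pseudocounts of 0.25 and 5, the authors' log2 fold change, mean FPKM limits of 1, 20 and none, 1.5-fold and 4-fold limits, other limits on the authors' calls, genes without overlap, protein-coding genes, and both together.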

Results

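Messenger RNA of 4 cultures was sequenced, 2 of A2780_DDP and 2 of SKOV-3_DDP. Both, named here as in the sample titles, are human ovarian cancer lines that resist cisplatin, the platinum drug that crosslinks DNA. In each line 1 culture received a small interfering RNA against keratin 14 (KRT14, a keratin of basal epithelial cells) and 1 a control RNA, and RNA was taken after 24 h. There are no replicates, so no value below has a spread between replicates, and a difference between 2 libraries has no replicate check. The tables hold FPKM (fragments counted per gene, divided by gene length and library size) for the genes the authors called, 440 in A2780_DDP and 420 in SKOV-3_DDP. Steps in the low FPKM values put the best fitting depth at 26310000 fragments for the library titled A2780_DDP-siKRT14 and 26970000 for A2780_DDP-siNC. The corresponding estimates were 27350000 for SKOV-3_DDP-siKRT14 and 37440000 for SKOV-3_DDP-siNC. These depths are estimates, because only 31.4%, 30.4%, 24.0% and 26.6% of the low genes came out whole within 0.03 of a fragment.

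LRP11, a membrane protein named for its relation to the low-density lipoprotein receptor family, was lower in the library whose title ends in siKRT14 (below, titled siKRT14) in both lines. In A2780_DDP its level was 4.64 FPKM in the library titled siKRT14 and 16.9 FPKM in the library titled siNC, 3.17-fold lower on the FPKM + 1 scale. SKOV-3_DDP gave 5.41 FPKM and 18.1 FPKM in the same order, 2.98-fold lower. At the estimated depths these levels correspond to 444 and 1652 fragments in A2780_DDP and to 538 and 2468 fragments in SKOV-3_DDP. The authors' deposited table gave a log2 fold change of -1.86 with adjusted p = 5.8e-66 for A2780_DDP, and -1.74 with adjusted p = 2.0e-85 for SKOV-3_DDP. Those p-values compare 1 library with 1 library, not the conditions. LRP11 (ENSG00000120256) lies on chromosome 6 from 149818757 to 149864359, minus strand, in coordinates that match GRCh38, and shares exonic sequence on its strand with 2 unnamed loci of GENCODE 29, AL355312.4 and AL355312.5.

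The series title states the opposite direction, an increase of LRP11 upon KRT14 knockdown, and the sample labels disagree among themselves. In 4 of 4 libraries the treatment label names the other siRNA than the title, and in 4 of 4 the genotype label goes with the treatment label, against the title. Libraries are therefore named here by their titles, which the authors' tables also use, and every direction below would turn if the treatment and genotype labels were right. KRT14 was not analysed here, so the targeted gene gives no check of either label. Among the other type I keratins, KRT16 was listed in A2780_DDP, at 0.445 FPKM in the library titled siKRT14 and 0.928 FPKM in the other. None of the 14 type II keratins on the list was listed in either line.

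The comparison in A2780_DDP asks which transcripts differ when KRT14 is silenced in these resistant cells. The widest difference was in ARF6, a small GTPase of membrane traffic at the cell surface, at 34.2 FPKM in the library titled siKRT14 and 0.560 FPKM in the library titled siNC, 22.6-fold higher on the FPKM + 1 scale. EIF3K, a subunit of translation initiation factor eIF3, stood at 20.2 against 0.702 FPKM, 12.4-fold higher. The interferon-induced RNA-binding protein IFIT5 was 5.58-fold higher, at 17.97 against 2.40 FPKM. On the other side TXNDC5, a protein disulfide isomerase of the endoplasmic reticulum, was 8.48-fold lower, at 8.59 against 80.4 FPKM. The nuclear pseudogene MTATP6P1, a copy of the mitochondrial ATP6 gene, was 9.22-fold lower, at 116 against 1081 FPKM.

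The authors' deposited table marked 211 genes up and 229 down in the library titled siKRT14, of which 353 are protein-coding, 57 long noncoding and 25 pseudogenes. A mean level of at least 5 FPKM was reached by 150 genes, and of these 63 were at least 2-fold higher and 60 at least 2-fold lower on the FPKM + 1 scale. Requiring a mean of 20 FPKM left 16 and 23, and a pseudocount of 5 left 32 and 29. The genes with the highest ratios also included ZNF24, a zinc finger transcription factor, at 20.1 against 3.94 FPKM, and SPIN1, a reader of histone methylation, at 76.3 against 17.98 FPKM. DRAM1, a lysosomal regulator of autophagy, was 3.61-fold higher at 37.5 against 9.66 FPKM. MSRB3, a methionine sulfoxide reductase, stood at 12.9 against 2.29 FPKM, and the Golgi membrane protein YIPF6 at 15.2 against 3.52 FPKM. PYURF (18.9 against 2.09 FPKM) shares exons with PIGY, and RRP7BP (13.9 against 2.18 FPKM) is itself a pseudogene.

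Lower genes included RAB31, a GTPase of endosomal traffic, at 5.94 FPKM in the library titled siKRT14 and 29.6 FPKM in the other, 4.41-fold lower. POFUT1, the O-fucosyltransferase that modifies Notch, was 4.25-fold lower (3.20 against 16.8 FPKM). HNRNPH2, a splicing regulator, stood at 14.4 against 63.2 FPKM, and the zinc transporter SLC39A1 at 21.1 against 75.3 FPKM. BTG1, an antiproliferative factor, was 3.48-fold lower at 3.68 against 15.3 FPKM, and EMP1, an epithelial membrane protein, 3.44-fold lower at 4.99 against 19.6 FPKM. C22orf46 was at 1.52 against 10.9 FPKM. TXNDC5, HNRNPH2, POFUT1, SLC39A1, BTG1 and MTATP6P1 overlap exons of another gene on their strand, and EIF3K has 3 named pseudogenes. Reads of these loci could be shared with the overlapping gene or a pseudogene, which was not tested for single genes. Those of the pseudogenes MTATP6P1 and RRP7BP could also be shared with the gene each copies, which was not tested either.

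Of the gene lists fixed before the data were examined, few members were listed in A2780_DDP. In this line 440 of the 13495 genes taken as tested were listed, so a short list would hold few or none in any case. Of 21 mesenchymal markers 2 were listed: the transcription factor ZEB1 was 2.96-fold higher (11.9 against 3.34 FPKM), and TWIST2, under the mean of 5 FPKM, stood at 0.813 against 2.66 FPKM. In the BCL2 family the pro-apoptotic PMAIP1 was 3.07-fold lower, at 20.03 against 63.5 FPKM, and no other member of the 16 was listed. The hemidesmosome linker PLEC was 2.33-fold lower (15.4 against 37.2 FPKM). FOSL2, an AP-1 subunit and the listed one of 22 immediate early genes, was 3.63-fold lower at 14.3 against 54.4 FPKM. IFIT5 was the listed one of 36 interferon-stimulated genes. TFRC, the transferrin receptor from the housekeeping list, was 2.20-fold higher at 106 against 47.7 FPKM. No platinum transporter or nucleotide excision repair gene of the lists was listed in this line.

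In SKOV-3_DDP the widest difference was in PTP4A1, a prenylated tyrosine phosphatase, at 0.210 FPKM in the library titled siKRT14 and 34.5 FPKM in the library titled siNC, 29.4-fold lower on the FPKM + 1 scale. PTP4A1 has 7 named pseudogenes and overlaps the exons of 1 unnamed locus. The GTPase RHOQ was 5.32-fold lower (2.78 against 19.1 FPKM), and GCH1, the first enzyme of tetrahydrobiopterin synthesis, stood at 1.63 against 9.50 FPKM. Higher in the library titled siKRT14 were RAB5B, a GTPase of early endosomes, 5.22-fold at 17.5 against 2.53 FPKM, and GPX1, the cytosolic glutathione peroxidase, 4.09-fold at 97.3 against 23.1 FPKM. LRRC8D, a subunit of the volume-regulated anion channel that also carries cisplatin into cells, was 4.03-fold higher, at 13.6 against 2.63 FPKM.

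For SKOV-3_DDP the authors' deposited table marked 200 genes up and 220 down, of which 359 are protein-coding, 42 long noncoding and 17 pseudogenes. Of the 150 genes with a mean of at least 5 FPKM, 66 were at least 2-fold higher and 64 at least 2-fold lower in the library titled siKRT14. At a mean of 20 FPKM the counts were 19 and 11, and with a pseudocount of 5 they were 35 and 37. DDIAS, a DNA damage-induced suppressor of apoptosis, was 4.23-fold higher (14.9 against 2.75 FPKM). REPIN1 stood at 25.6 against 5.42 FPKM and the pyridoxal phosphatase PDXP at 10.7 against 1.88 FPKM. MTATP6P1 was higher here, at 439 against 95.2 FPKM. The pseudogene MEMO1P1 (16.4 against 1.86 FPKM) and the read-through locus ARPIN-AP3S2 (15.3 against 1.76 FPKM) had the highest ratios among named genes that passed the level rule. AP3S2, which shares exons with that locus, was at 3.49 against 7.89 FPKM, the other direction. Lower genes included MSRB3 (2.24 against 13.3 FPKM), the proteasome ATPase PSMC4 (4.86 against 22.2 FPKM) and LEPROT (4.90 against 21.9 FPKM), which overlaps the leptin receptor gene. MPZL1, a membrane glycoprotein of the myelin protein zero family, was at 3.57 against 15.8 FPKM, the homeobox gene HOXB3 at 3.35 against 13.5 FPKM and the mitochondrial import factor GRPEL2 at 2.38 against 10.3 FPKM. The pseudogene GTF2IP1 was at 3.47 against 14.2 FPKM. Exons of another gene on the same strand overlap those of LRRC8D, REPIN1, DDIAS, PDXP, HOXB3, LEPROT, MTATP6P1 and GTF2IP1. RHOQ and GRPEL2 have 3 named pseudogenes each, and GPX1 has 2. Reads of all these loci could be shared with the overlapping gene or a pseudogene, which was not tested for single genes. Those of the pseudogenes MTATP6P1, MEMO1P1 and GTF2IP1 could also be shared with the gene each copies, which was not tested either.

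The lists again had few listed members in SKOV-3_DDP, where 420 of the 14574 genes taken as tested were listed. Short lists would hold few or none at that share, so these counts are not results about the groups. Both listed genes of the BCL2 family are anti-apoptotic, and both were higher in the library titled siKRT14. MCL1 was 2.55-fold higher, at 43.3 against 16.4 FPKM, and BCL2L2 stood at 7.21 against 2.33 FPKM, a mean under 5 FPKM. ERCC4, the repair endonuclease subunit XPF, was the listed one of 19 nucleotide excision repair genes, at 2.81 against 1.01 FPKM. LRRC8D was the listed one of 18 platinum transport genes. In the lipoprotein receptor family LRP6, a Wnt co-receptor, was at 0.324 against 3.77 FPKM. The mitotic gene NUSAP1 was 2.18-fold higher (95.8 against 43.3 FPKM), and MXI1, a MYC antagonist induced by hypoxia, 1.91-fold higher (14.5 against 7.12 FPKM). MCL1, BCL2L2 and NUSAP1 overlap exons of another gene on their strand. The interferon-stimulated genes XAF1, IFI44L and MX2 were lower, but at 0.260, 0.173 and 0.148 FPKM against 1.31, 0.552 and 0.393 FPKM. Across both lines 20 of the 35 lists had no listed member. These were the lists of type II keratins, epithelial adhesion, glutathione and NRF2 targets, homologous recombination, p53 targets and NF-kB targets. Further ones were the ATF4 and unfolded protein response, cholesterol and fatty acid synthesis, and Wnt, YAP and heat shock targets. The rest were nuclear respiratory chain subunits, the 13 genes of the mitochondrial genome, replication-dependent histones, and ovarian, stem, haematopoietic, endothelial and fibroblast markers. A list holds only a part of its group, so a list without a listed member does not mean that its group has none. In SKOV-3_DDP the glutathione peroxidase GPX1 was listed but is in none of the lists. PMAIP1 and DRAM1 were listed in A2780_DDP but are not on the list of p53 targets. A gene that is not listed has no value here, so its level was not compared.

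**Figure D1:**
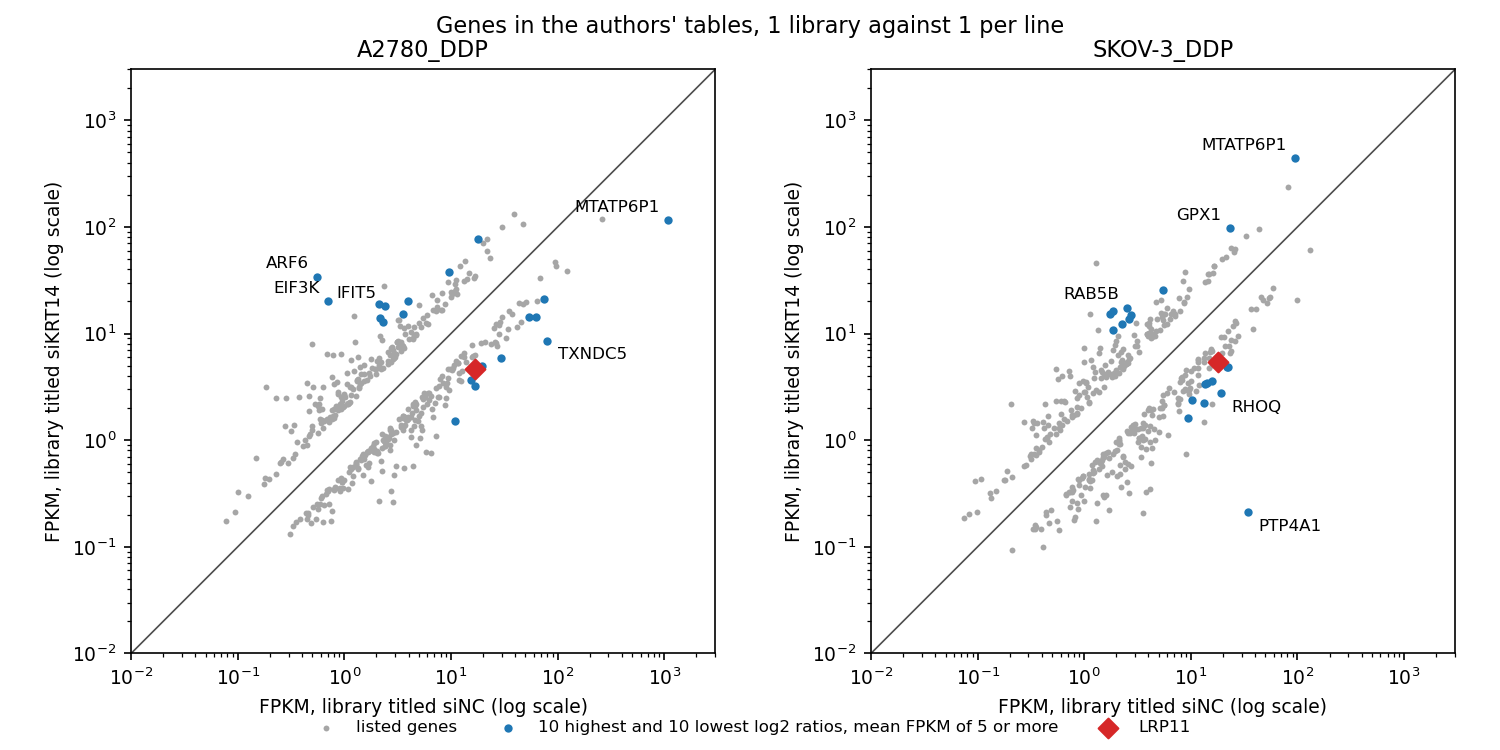
FPKM in the library titled siNC (x axis) and in the library titled siKRT14 (y axis), both log scales, for the 440 genes listed in A2780_DDP (left) and the 420 listed in SKOV-3_DDP (right), 1 point per gene; the line marks equal levels. Blue points are the 10 highest and 10 lowest log2 ratios among named genes with a mean of 5 FPKM or more, and LRP11 (red diamond) lies below the line in both lines, at 4.64 against 16.9 FPKM and 5.41 against 18.1 FPKM.

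Setting both lines side by side asks which differences they share. YIPF6, PIP4K2C, KIAA1191 and SNHG30 were higher in the library titled siKRT14 in both lines, and LRP11, LGR4, DCTN4 and GJC1 were lower in both, at a mean of 5 FPKM or more in each. These 8 are all the genes with a symbol that met this rule. YIPF6 was 3.59-fold higher in A2780_DDP and 3.50-fold higher in SKOV-3_DDP, where it stood at 20.7 against 5.21 FPKM. The lipid kinase PIP4K2C was 2.30-fold higher in A2780_DDP and 2.19-fold in SKOV-3_DDP, KIAA1191 2.25-fold and 2.08-fold, and the noncoding RNA SNHG30 1.92-fold and 1.98-fold. LGR4, a receptor for R-spondins that strengthens Wnt signalling, was 2.76-fold lower in A2780_DDP (3.66 against 11.8 FPKM) and 2.56-fold lower in SKOV-3_DDP (8.77 against 24.0 FPKM). The dynactin subunit DCTN4 was 2.38-fold and 2.77-fold lower and the connexin gene GJC1 2.13-fold and 2.06-fold lower. FPKM tables were made separately for each line, so levels are compared within a line only.

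Between the lines 68 genes were listed in both, against 13.7 that the list sizes give by chance if the same 13495 genes were tested in each. Of these, 24 had the same direction (18 higher in both, 6 lower in both) and 44 opposite directions. Opposite directions thus made up 64.7% (95% Wilson interval 52.8% to 75.0%, counting error only). The split of directions of these 68 genes within each line gives 48.6%. Among the 20 genes at a mean of 5 FPKM and 2-fold in both lines, 7 had the same and 13 the opposite direction, next to 10.6 opposite from their own split. Across the 26 shared genes with a mean of at least 5 FPKM in both lines, Pearson's r of the log2 ratios was -0.50 and Spearman's rho -0.48. Genes are not independent replicates, and the tables leave out genes with small differences, so no p is given. A choice made after seeing the data kept genes of any biotype free of exon overlap on their own strand. Among these r was -0.29, with 6 genes 2-fold in the same and 8 in opposite directions. Restricting these to protein-coding genes gave -0.19, with 6 and 7.

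**Figure D2:**
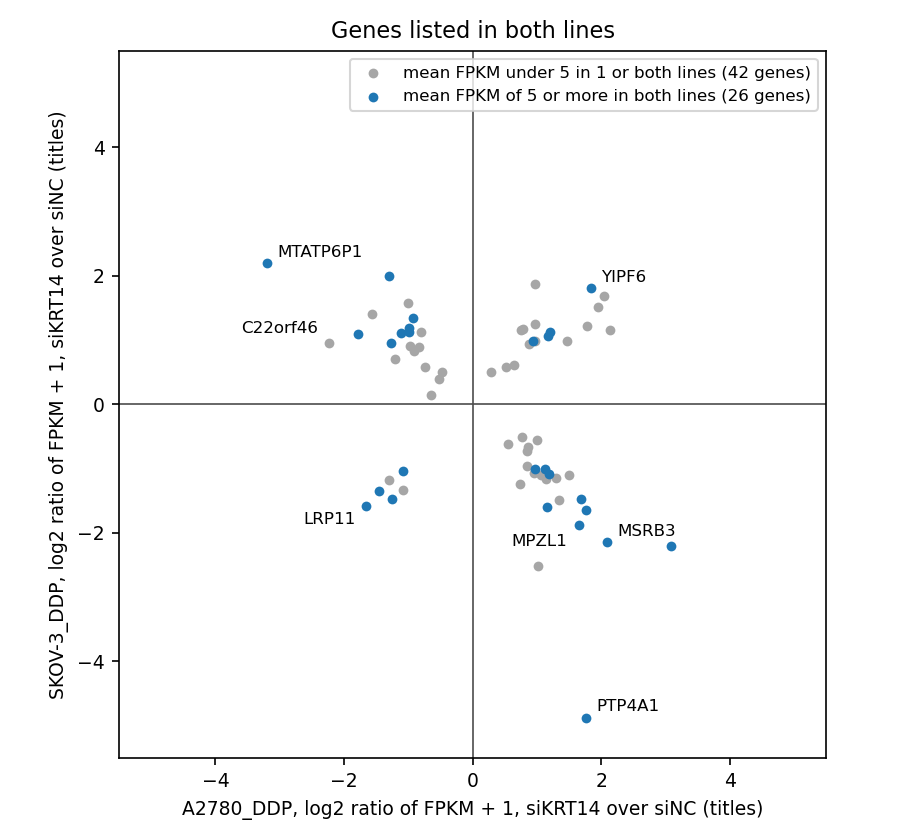
Log2 ratio of FPKM + 1, library titled siKRT14 over library titled siNC, in A2780_DDP (x axis) and SKOV-3_DDP (y axis) for the 68 genes listed in both lines, 1 point per gene. Points in the upper left and lower right quadrants (44 genes) have opposite directions in the lines, LRP11 lies in the lower left at -1.66 and -1.58, and PTP4A1 lies at 1.76 and -4.88.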

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

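The test of labels exchanged in 1 line and that of the labels behind LRP11 were chosen after the result was seen. Each gene below differed between the lines in the direction of its siKRT14 to siNC ratio, with 1 library per group in each line, and the difference was not tested. Values are the log2 ratio of FPKM + 1 in A2780_DDP minus that in SKOV-3_DDP. For PTP4A1 this difference was 6.64 (70.4 against 20.1 FPKM in A2780_DDP and 0.210 against 34.5 FPKM in SKOV-3_DDP). MSRB3 had 4.22 and MPZL1 3.54 (23.03 against 6.61 FPKM in A2780_DDP). MTATP6P1 had -5.40, C22orf46 -3.19 (2.65 against 0.892 FPKM in SKOV-3_DDP) and SLC39A1 -2.88 (19.3 against 8.56 FPKM in SKOV-3_DDP).

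These 6 belong to the 68 genes listed in both lines, of which 64.7% had opposite directions. Reads shared between overlapping genes may account for part of this set, but the comparison does not address direction. Of genes found in GENCODE 29, 27 of 67 shared genes (40.3%) overlap an exon of another gene on their strand. The share was 200 of 696 among genes listed in 1 line (28.7%), a difference of 11.6 percentage points (95% Newcombe interval 0.12 to 24.0). The interval treats genes as independent, although some shared genes overlap each other, as ZNF23 and ENSG00000261611 do, so it may be too narrow. In GENCODE 29 MSRB3, MPZL1 and C22orf46 have no such exon overlap. Whether MTATP6P1 shares reads with the mitochondrial ATP6 gene it copies was not tested. Abundance stays open, since the median level of shared genes was 1.48 times that of the others (95% bootstrap interval 1.09 to 2.68), which neither reaches nor excludes the bound of 1.5 set beforehand. An exchange of the siRNA labels in 1 line would turn opposite into same directions. It cannot be told apart from other causes, because KRT14 was not analysed. Genes of the same direction numbered 24 where the list sizes give 6.86, but those of opposite directions exceeded that chance value too (44 against 6.83). The 24 genes therefore do not bear on an exchange. A different response of the lines is the biological explanation the design gives, and it was not tested.

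The direction of LRP11 is the value on which the series title can be compared with the tables. The treatment label names the other siRNA than the title in 4 libraries, and the genotype label goes with it, so titles and treatments exchanged in the labels could give a lower LRP11 in the libraries titled siKRT14. With the treatment labels LRP11 would be 3.17-fold and 2.98-fold higher after KRT14 silencing. Which label is right cannot be told apart here, because KRT14 was not analysed.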

How the results depend on the processing

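The alternatives by overlap and biotype were chosen after the data were seen. No pseudocount can turn the direction of LRP11, and the authors' ratio is the same FPKM with 0.01 added. Its log2 ratio (-1.66 in A2780_DDP, -1.58 in SKOV-3_DDP) was -1.81 and -1.70 with a pseudocount of 0.25, -1.18 and -1.15 with 5, and -1.86 and -1.74 in the authors' deposited table.

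Counts of genes at 2-fold, given as A2780_DDP higher, A2780_DDP lower, SKOV-3_DDP higher and SKOV-3_DDP lower, were 63, 60, 66 and 64. A pseudocount of 5 gave 32, 29, 35 and 37. A mean of 1 FPKM gave 100, 91, 101 and 106, a mean of 20 FPKM gave 16, 23, 19 and 11, and no level rule gave 100, 91, 101 and 108. A 4-fold limit gave 10, 6, 13 and 6. Genes of any biotype without overlap gave 49, 38, 46 and 45, protein-coding genes 56, 55, 61 and 60, and both limits together 45, 36, 43 and 43. A pseudocount of 0.25 gave 73, 66, 73 and 72. The authors' ratio and a 1.5-fold limit admit all 150 genes per line at the level rule, since the tables hold no smaller difference, so they test nothing. The level and fold limits act by admitting fewer or more genes, and a larger pseudocount by shrinking each ratio. The authors' calls (211, 229, 200 and 220) all pass an absolute log2 fold change of 1 and adjusted p of 0.05 by construction of the tables, and were 37, 25, 36 and 42 at 2 and 0.01.

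Between the lines r was -0.50, with 7 genes 2-fold in the same and 13 in opposite directions. It was -0.48 with a pseudocount of 0.25, -0.46 with the authors' ratio, -0.57 with 5 (2 and 8 genes), -0.32 at a mean of 1 FPKM (13 and 21), -0.33 with no level rule (13 and 21), -0.29 without overlapping genes of any biotype (6 and 8), -0.40 for protein-coding genes (7 and 10) and -0.19 with both limits (6 and 7). At 20 FPKM 1 gene had the same and 4 opposite directions, too few for r. The sign stayed negative in each setting run, and the cause of the shifts was not tested. List member counts moved by over 1.5 times at 20 FPKM in both lines, and for genes lower in SKOV-3_DDP at 1 FPKM and with no level rule.

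The model that pairs the libraries by line, with its alternatives, was not run, as fixed beforehand for tables of called genes. A fit to the 68 shared genes was left out, as these had been selected for their differences. The TMM, DESeq2 and total-count scalings and the list percentiles were not run because they need counts or the other genes. The KRT14 ratio was not analysed here. Depth is known as an estimate alone, and at 0.210 FPKM the low PTP4A1 value rests on an estimated 27 fragments.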

Other observations

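Genes in this part were chosen after their values were seen, except LRP6, ARF6, EIF3K, TXNDC5, PTP4A1 and MTATP6P1. Below a mean of 5 FPKM in 1 or both lines, further genes were higher in the library titled siKRT14 in both lines. RBM15, an RNA-binding protein of the m6A methyltransferase complex, stood at 8.29 against 1.25 FPKM in A2780_DDP and 6.61 against 1.38 FPKM in SKOV-3_DDP. NUDT16, a decapping enzyme, stood at 6.42 against 0.923 FPKM and 3.96 against 0.741 FPKM. The end-joining ligase LIG4 was at 5.35 against 2.23 FPKM and 4.38 against 1.26 FPKM. MTAP, the enzyme of methionine salvage, was lower in both, at 2.55 against 7.70 FPKM in A2780_DDP and 1.64 against 5.001 FPKM in SKOV-3_DDP.

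Other shared genes were opposite. The transcription factor ADNP was higher in A2780_DDP (18.5 against 5.04 FPKM) and lower in SKOV-3_DDP (5.20 against 16.2 FPKM), as was the membrane protein CLPTM1L (18.9 against 8.87 FPKM and 0.737 against 8.98 FPKM). The osmotic stress factor NFAT5 was lower in A2780_DDP (4.72 against 10.3 FPKM) and higher in SKOV-3_DDP (7.68 against 2.97 FPKM), and the mitochondrial ribosomal gene MRPL49 likewise (12.8 against 28.9 FPKM and 30.5 against 13.6 FPKM).

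Of pairs of listed genes whose loci overlap on 1 strand, 7 of 11 in A2780_DDP and 8 of 13 in SKOV-3_DDP had opposite directions, where the split of directions in each list gives 5.503 and 6.501. In SKOV-3_DDP 3 of the pairs are among the same protocadherin gamma genes. BCAP29 was lower in A2780_DDP (1.34 against 3.60 FPKM) while its read-through locus DUS4L-BCAP29 was higher (2.49 against 0.230 FPKM), and in SKOV-3_DDP BCAP29 was higher (4.87 against 2.14 FPKM) and DUS4L-BCAP29 lower (1.10 against 3.48 FPKM). The 2 gene IDs named MATR3 stood at 12.5 against 26.5 FPKM and 49.5 against 19.5 FPKM in SKOV-3_DDP.

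At 8-fold or more in the authors' deposited table there were 15 genes in A2780_DDP (10 up, 5 down) and 13 in SKOV-3_DDP (6 up, 7 down). For low abundance, the median of their mean FPKM was 2.07 times that of the other listed genes. The 95% bootstrap interval, 0.80 to 3.46, lay above the bound of 0.67 set beforehand. The mean of 2 libraries mostly follows the higher one, so this cannot decide whether low values in the other library widened these ratios. Reads shared between overlapping genes may account for part: of those found in GENCODE 29, 14 of 27 overlap an exon on their strand (51.9%), against 213 of 736 others (28.9%), a difference of 22.9 percentage points (95% Newcombe interval 4.73 to 40.6). That interval treats genes as independent. ARF6 and LRP6 have no such exon overlap in GENCODE 29, and PTP4A1, TXNDC5 and MTATP6P1 do. EIF3K has none but has 3 named pseudogenes. A change of these genes by the siRNA was not tested, since there is 1 library per group.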
